A study of Mus musculus with 4 samples.

How the data were processed

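RNA of the gastric and of the pancreatico-duodenal lymph node of 4 female NOD mice was amplified, labelled with Cy5 and Cy3 respectively and hybridised to 1 two-colour Agilent array per mouse, per the labels' protocols. The 4 arrays lay on 1 slide and were scanned together, per the file headers, so no comparison between slides or scans could be made. The deposited scanner files hold, for each of 45018 spots, the mean and background intensity in both channels, per the file headers made with Agilent Feature Extraction 10.2.1.3. The same files hold the authors' processed intensity, after the software's background subtraction and dye normalization, and the log10 ratio of Cy5 over Cy3 computed from it, per the file headers. The authors' deposited series table holds a log2 value for each probe and array. Each value equalled the log2 ratio of the processed Cy5 over Cy3 signals averaged over a probe's spots, with a largest difference of 5.1e-05. Its scale and direction were settled in this way, and its column medians were -0.15, -0.06, -0.03 and -0.03 for mice 1 to 4.

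Mean and background median intensities were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3, with the package data.table (version 1.17.8) for reading files. Control spots and outlier-flagged spots had weight 0 in loess, and outlier-flagged spots were then left out. No step between arrays was applied. Spots of the same probe were averaged, which gave 41174 probes. A probe was kept if it was well above background in the same channel on at least 3 of 4 arrays, which left 27603 probes.

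Probes were named through their transcript accession, matched without version to a RefSeq gene table of the assembly GRCm38.p6, used for names only. The design written beforehand had assumed gene names in the scanner files, which carry accessions instead. A symbol was found for 24844 probes, and the other 16330 kept their accession as a feature of their own and are counted but not named. No coordinates are given, since the array annotation and the gene table use different builds. For several probes of a gene the one with the highest mean intensity was used. This left 21320 features, 13400 of them with a symbol. Of 382 called genes with further kept probes, 311 had the same sign on all probes.

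The log ratio pairs both nodes of a mouse on 1 array. Each feature's mean log2 ratio over the 4 mice was tested against 0 with lmFit and eBayes, adjusted by the Benjamini-Hochberg method, at a threshold of 0.05. Values are given as mean ± SD over mice. Gene lists fixed beforehand for the cell types and tissues that a node or its surroundings can hold and for immune and housekeeping pathways were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists with at least 4 measured members. The immunoglobulin list had no matched gene and was not tested. Of the 38 lists 15 were shifted, 13 lower and 2 higher in the gastric node, and none was with an estimated correlation. The rotation test fry, which asks whether the genes of a list move one way on balance, called 2 lists, circadian clock and ribosomal protein, and its mixed form, which asks for change in either direction, called 28. Neither compares a list with other genes.

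Named genes were chosen by a rule fixed before the data were examined. It took the 12 largest called increases and decreases with the same sign in every mouse, skipping accessions and clone, predicted and uncharacterised names, up to 4 called members of each list, or up to 2 of the brightest where none was called, and a fixed set of genes of interest. Skipped names made up 357 of the 659 higher and 146 of the 949 lower features, and 9 and 1 of them were larger than the last gene named in each direction.

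The steps were tested on simulated intensities for 21320 features with an invented dye curve. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 65.7%, 98.5% and 98.5% of changed genes, and the median fitted size of a change of 1 was 0.784. Of 192 calls 15 were false. None of 20 unchanged lists was called, and the 1 list shifted by 0.3 was called. Simulated genes varied independently of each other, whereas the macrophage list of the real data had an estimated correlation of 0.51. False list calls from correlated genes could therefore not show in the simulation.

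Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, the choice of probe, each mouse left out, the variance model, the pairing, the threshold, the series table and the set test. Probe sequences were not used here, so a correction for base content was not run.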

Results

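Expression was compared between 2 lymph nodes that drain the pancreas in the NOD mouse, an inbred strain that spontaneously develops autoimmune diabetes. The gastric lymph node is the left pancreatic node and the pancreatico-duodenal lymph node is the right one. Both nodes were taken from each of 4 female mice aged 12 weeks. Each mouse had its own two-colour array, with gastric node RNA in the red Cy5 channel and pancreatico-duodenal node RNA in the green Cy3 channel. Every log2 ratio below is gastric over pancreatico-duodenal node, so a negative value means a lower level in the gastric node. The dyes were not exchanged on any array, so an effect of the dye and an effect of the node could not be separated for any gene. The share of probes well above background ranged from 67.1% to 71.4% in the gastric node channel and from 59.6% to 62.6% in the pancreatico-duodenal node channel. The median mean signal of a spot was 115 to 155 in the gastric node channel and 87.3 to 95.9 in the other. No spot was saturated, and the number of arrays, 4, limited the precision.

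The comparison asked which genes differ in level between the left and the right pancreatic node of the same mouse. The largest called difference was that of Apol7c, an apolipoprotein L family gene, which was 10.3-fold lower in the gastric node (log2 ratio -3.36 ± 0.57, SD, n = 4; adjusted p = 0.0157). Aldh1a2, which encodes a retinaldehyde dehydrogenase that makes retinoic acid, was 3.22-fold lower (-1.69 ± 0.34, SD, n = 4; adjusted p = 0.0198). Macrophage genes were also lower, among them Adgre1, which encodes F4/80, at -1.36 ± 0.71 and the haemoglobin scavenger receptor gene Cd163 at -1.26 ± 0.30 (SD, n = 4). In the other direction, Il22ra2, which encodes a soluble receptor that binds interleukin 22, was 2.21-fold higher in the gastric node (1.14 ± 0.47, SD, n = 4; adjusted p = 0.0311). Ifng, the gene of interferon gamma, was 1.68-fold higher (0.75 ± 0.28, SD, n = 4; adjusted p = 0.0295). Further probes read -2.48 for Apol7c, -0.54 for Adgre1, 0.42 for Il22ra2 and 0.51 for Ifng.

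Of 21320 genes and unnamed transcripts tested with limma, 659 were higher and 949 were lower in the gastric node at an adjusted p under 0.05. Each of these 1608 had the same sign in 4 of 4 mice, which the threshold itself nearly requires with so few mice. The median log2 ratio was 0.30 for the higher and -0.38 for the lower ones. A difference of more than 2-fold was found for 2 of the higher and 21 of the lower ones. Without mouse 2 no gene passed (4343 at an unadjusted p under 0.05), without mouse 3 only 3 lower features passed and without mouse 4 only 1, Dnah2, while without mouse 1 the counts were 844 and 1323. The 3 that passed without mouse 3 were Apol7c, Fndc5 and 1 unnamed transcript, with Fndc5 at -1.13 there (Fndc5 was singled out after its values were seen). Scaling the 4 arrays to a common spread also left no call, with 6238 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0628. With median centring in place of loess the median of all features moved to 0.32. There 11 named genes lost the call without a change of sign. Another 18 turned sign among those called in either setting, and of these Eng, Esam, Per1, Plvap and Tap2 also lost the call. Relative to the median of all features, 80 of 81 called named genes and 12 of 15 called lists kept the direction given here.

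The other large decreases in the gastric node took in several kinds of gene. Dnah2, an axonemal dynein heavy chain gene, was at -1.99 ± 0.41, Inmt, which encodes an indole methyltransferase, at -1.64 ± 0.69 and Efemp1, an extracellular matrix glycoprotein gene, at -1.56 ± 0.35 (SD, n = 4). Wfdc17 and the hexokinase gene Hk3 were both at -1.37, with SDs of 0.38 and 0.42. Itga2b, the integrin alpha IIb gene of platelets and megakaryocytes, was at -1.30 ± 0.36. The dipeptidase gene Dpep1 was at -1.17 ± 0.14 and the scavenger receptor gene Scara5 at -1.16 ± 0.45. All 8 passed, with adjusted p values from 0.0148 for Dpep1 to 0.0313 for Inmt.

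The largest called increase among named genes was that of Ppp1r14c. This gene, which encodes an inhibitor of protein phosphatase 1, was at 1.23 ± 0.66, and the transcription factor gene Creb3l3 at 1.00 ± 0.55 (SD, n = 4). Folr2, the folate receptor beta gene of macrophages, was at 0.74 ± 0.36. The natural killer receptor gene Klra7 was at 0.71 ± 0.36 and Trem2, a myeloid receptor gene, at 0.62 ± 0.32. Sh2d1a, which encodes the adaptor SAP of T cells, was at 0.58 ± 0.21. Rpl12 (0.64 ± 0.06), Ptma (0.60 ± 0.14), Dcaf12l2 (0.60 ± 0.12) and Lars2 (0.58 ± 0.20) completed the group. Rpl12 and Lars2 were very bright, with mean log2 intensities of 17 and 17.9 over both channels. Bright features read higher as a group, with median log2 ratios of 0.21 at intensities from 16 to 17 and 0.45 above 17. The further probes read only -0.0045 for Dcaf12l2, 0.07 for Ptma and 0.33 for Trem2. All 10 passed, with adjusted p values from 0.0198 for Rpl12 to 0.0465 for Creb3l3.

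**Figure D1:**
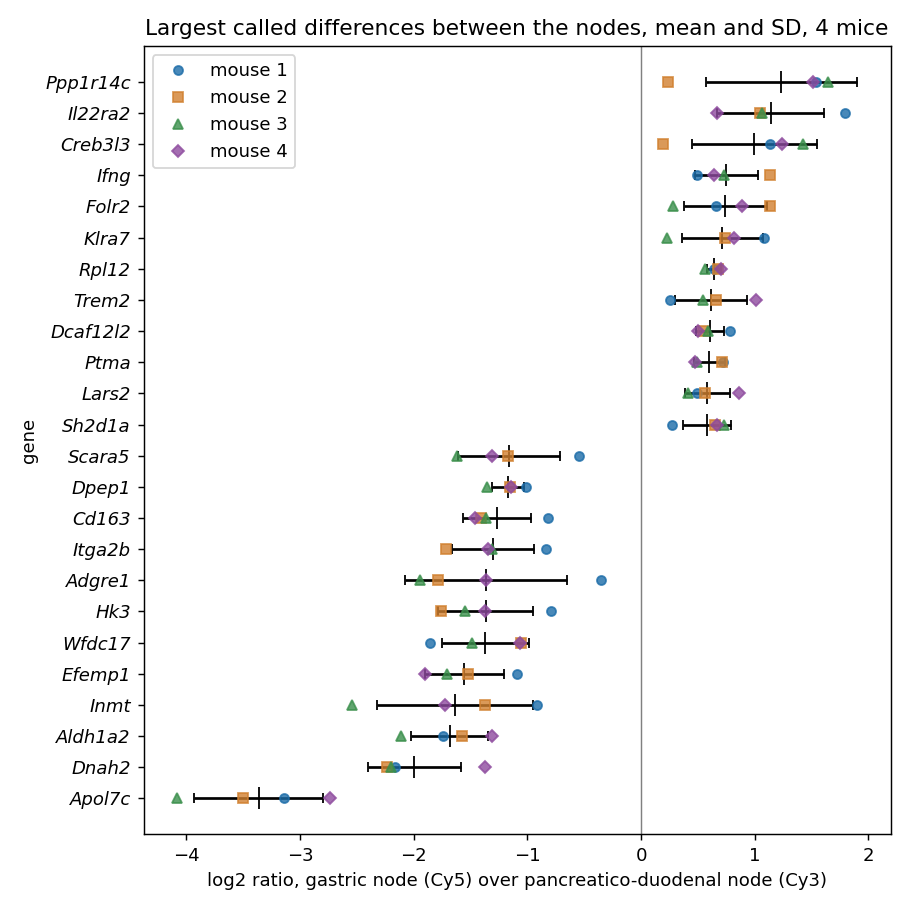
Log2 ratio of gastric over pancreatico-duodenal node (horizontal axis) for the 12 named genes with the largest called increase and the 12 with the largest called decrease. Coloured symbols are the 4 mice, the vertical tick is their mean and the bar is the SD. Apol7c lies lowest, between -4.08 and -2.73, and every symbol lies on its gene's side of 0, as the naming rule required.

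Genes of macrophages and monocytes were lower in the gastric node as a group. Of 23 measured members, 10 were lower, 1 was higher and 12 did not pass; adjusted over the list alone, 16 were lower and 2 higher. Besides Cd163 and Adgre1, the complement genes C1qb (-1.04 ± 0.26, SD, n = 4) and C1qa (-0.93 ± 0.22) were lower, and Folr2 was the member that was higher. The list median was -0.43, and the list was shifted against all other genes (camera, adjusted p = 8.17e-08), a call that was lost with an estimated correlation (adjusted p = 0.610 with an estimated correlation of its genes). The list median was below 0 in each mouse, at -0.21, -0.37, -0.94 and -0.59 in mice 1 to 4. Mouse 3, with the lowest value, was also the mouse whose exocrine pancreas genes were far lower on the gastric side, and the mean of the list medians of the other mice was -0.39 ± 0.19 (SD, n = 3).

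Dendritic cell genes were lower too, with 6 of 19 members lower, none higher and 13 not passing (9 lower adjusted over the list alone). Next to Aldh1a2, the called members included Fscn1, an actin-bundling gene of mature dendritic cells (-0.65 ± 0.30, SD, n = 4), the growth factor receptor gene Flt3 (-0.64 ± 0.20) and Snx22 (-0.57 ± 0.13). With median centring Fscn1 and Snx22 lost the call, while Aldh1a2 and Flt3 kept it. Fscn1 also lost it with the scanner software's ratio and the authors' series table. The camera test gave an adjusted p = 1.99e-05, and an adjusted p = 0.610 with an estimated correlation. Markers chosen for spleen were shifted the same way (2 of 8 lower, none higher; 5 lower adjusted over the list alone; camera adjusted p = 0.000301, and adjusted p = 0.610 with an estimated correlation). Its called members were Nkx2-3, a homeobox gene of gut and spleen vessels and stroma, at -0.90 ± 0.09 and Treml4 at -0.81 ± 0.25 (SD, n = 4). The means of the list medians without mouse 3 were -0.22 ± 0.09 for dendritic cells and -0.30 ± 0.14 for spleen (SD, n = 3).

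Some vessel and stromal genes were lower in the gastric node, while most members of each list did not pass. In lymphatic endothelium 6 of 13 members were lower and none was higher (9 lower adjusted over the list alone), led by the scavenger receptor gene Stab1 at -0.87 ± 0.32 (further probe -0.41) and Reln at -0.78 ± 0.33 (SD, n = 4). Blood endothelium had 4 of 21 members lower and none higher (10 lower and 1 higher adjusted over the list alone), among them the receptor gene Tie1 at -0.58 ± 0.07 and Plvap, a gene of endothelial diaphragms, at -0.54 ± 0.18. Fibroblastic stroma had 9 of 28 members lower and none higher (13 lower and 1 higher adjusted over the list alone), including the collagen genes Col3a1 (-0.84 ± 0.34) and Col1a1 (-0.61 ± 0.25) and the proteoglycan gene Bgn (-0.72 ± 0.14); further probes of Col3a1 and Col1a1 reached only -0.12 and -0.11. Camera gave adjusted p values of 1.38e-05, 7.63e-05 and 1.83e-06 for the 3 lists. All 3 calls were lost with an estimated correlation (adjusted p = 0.610, 0.623 and 0.623 with an estimated correlation), and that of blood endothelium also with median centring in place of loess. The single-gene calls of Col3a1, Col1a1 and Plvap were lost with median centring as well, and the sign of Plvap turned. So were those of the called members Itga9, Stab2, Eng and Esam, while Stab1, Reln, Tie1 and Bgn kept theirs. The stromal median was 0.02 in mouse 1 and between -0.51 and -0.25 in the other mice, and that of blood endothelium was -0.02 in mouse 1 and between -0.45 and -0.16 in the others. Lymphatic endothelium was at -0.14, -0.34, -0.30 and -0.61 in mice 1 to 4. In the same mice the adipocyte median was 0.99, -1.02, 0.00 and -0.82. Without mouse 3 the means of the list medians were -0.37 ± 0.24, -0.16 ± 0.14 and -0.21 ± 0.21 (SD, n = 3).

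Smaller groups of the same kind followed. Smooth muscle had 2 of 10 members lower (3 adjusted over the list alone), the intermediate filament gene Des at -0.46 ± 0.09 and Smtn at -0.41 ± 0.07 (SD, n = 4; camera adjusted p = 0.0146, and adjusted p = 0.610 with an estimated correlation). The smooth muscle call was also lost with median centring, as were the single-gene calls of Des and Smtn. The list median was 0.04 in mouse 1 and -0.30, -0.17 and -0.31 in mice 2 to 4. The mesothelium and epithelium list had 1 of 6 lower (3 adjusted over the list alone), the keratin gene Krt7 at -0.34 ± 0.09 (camera adjusted p = 0.00325, and adjusted p = 0.610 with an estimated correlation). Schwann cell and nerve genes had 1 of 9 lower, Prx at -0.22 ± 0.03, and the list was not shifted (camera adjusted p = 0.587; 2 higher and 1 lower adjusted over the list alone).

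Genes of mucosal homing and IgA were lower in the gastric node in 3 of 10 cases and higher in none (3 lower adjusted over the list alone). These were Aldh1a2, Itgae, which encodes the integrin CD103 of intestinal T cells and dendritic cells (-0.63 ± 0.14, SD, n = 4; adjusted p = 0.0223), and Madcam1, the vessel ligand for gut-homing lymphocytes (-0.25 ± 0.09; adjusted p = 0.0497). The Madcam1 call was lost in 13 of 19 alternatives, and its sign turned with median centring. The Itgae call was lost with median centring, without a turn of sign. The chemokine receptor gene Ccr9 was at -0.18 ± 0.22 and did not pass (adjusted p = 0.242). The IgA gene itself was not measured, since no immunoglobulin gene was matched. The list was shifted (camera adjusted p = 0.00550, and adjusted p = 0.610 with an estimated correlation), but the call was lost and its median turned above that of all features when the arrays were only median-centred.

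Plasma cell genes had 2 of 20 members lower and none higher (3 lower adjusted over the list alone), the receptor gene Tnfrsf17 at -0.33 ± 0.07 and the secretory transcription factor gene Xbp1 at -0.28 ± 0.11 (SD, n = 4). MHC and antigen presentation genes had 1 of 16 lower (3 lower and 1 higher adjusted over the list alone), the peptide transporter gene Tap2 at -0.44 ± 0.11. The camera adjusted p was 0.0294 and 0.0284 for these 2 lists, lost at adjusted p = 0.623 and 0.610 with an estimated correlation. With median centring in place of loess both list medians turned above that of all features, the plasma cell call was lost and the antigen presentation list was called in the other direction, as higher. Circadian clock genes had 4 of 16 lower and none higher (4 lower adjusted over the list alone), among them Per1 at -0.41 ± 0.08 and Hlf at -0.48 ± 0.25 (camera adjusted p = 0.0432, and adjusted p = 0.610 with an estimated correlation). The remaining called members, Npas2 (-0.22 ± 0.05) and Bhlhe41 (-0.24 ± 0.08), were dim. Npas2 was well above background on 1 of 4 pancreatico-duodenal and 3 of 4 gastric node arrays, and the Bhlhe41 call was lost in 10 of 19 alternatives. Without mouse 3 and without mouse 4 the circadian call was lost, as was the plasma cell call without mouse 4 and the antigen presentation call without mouse 2. Both the circadian and the plasma cell call were also lost with the filter on both channels and with unpaired channels. The circadian call was lost as well with median centring, the scanner software's ratio, the mean of a gene's probes and the authors' series table.

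T cell genes were higher in the gastric node in 2 of 25 cases and lower in none (2 higher adjusted over the list alone). They were the receptor component gene Cd3g at 0.32 ± 0.14 and the co-stimulatory receptor gene Cd28 at 0.33 ± 0.15 (SD, n = 4). The list was shifted (camera adjusted p = 0.0335, and adjusted p = 0.768 with an estimated correlation), but not without mouse 2, mouse 3 or mouse 4, and its median was -0.06 in mouse 1. This call was also lost with the scanner software's ratio, the mean of a gene's probes and the authors' series table. Cytotoxic and Th1 cell genes had 2 of 22 higher, Ifng and the receptor gene Klrd1 (0.29 ± 0.11), and the list was not shifted (camera adjusted p = 0.587; 2 higher adjusted over the list alone). In the germinal centre list 1 of 15 was higher, Sh2d1a, and the list was not shifted (camera adjusted p = 0.587; 2 higher and 1 lower adjusted over the list alone). None of 22 B cell genes passed, with Cd79b at 0.07 ± 0.20 and Blnk at 0.08 ± 0.16. In the regulatory T cell list 1 of 17 was lower, Itgae (1 higher and 4 lower adjusted over the list alone). Foxp3, the transcription factor gene of regulatory T cells, was at 0.24 ± 0.27 (adjusted p = 0.198) and Ctla4 at 0.03 ± 0.07 (adjusted p = 0.735). Of 30 proliferation genes 2 were higher, the replication genes Pcna at 0.33 ± 0.12 and Mcm4 at 0.33 ± 0.13 (2 higher adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.403).

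Genes of cytosolic ribosomal proteins were higher in the gastric node in 28 of 78 cases and lower in none (41 higher and 2 lower adjusted over the list alone). Rpl12, Rps18 (0.55 ± 0.10), Rps27 (0.50 ± 0.10) and Rpl37a (0.50 ± 0.08) were the largest (SD, n = 4), with a further probe of Rps18 at 0.21. The list was shifted (camera adjusted p = 2.29e-09, and adjusted p = 0.610 with an estimated correlation). Its call was also lost when features with a mean log2 intensity above 16 were left out, an alternative chosen after seeing the data. The ratio followed the brightness of the probe. The 37 members with a mean log2 intensity above 16 had a median of 0.31 and 26 of them were higher, while none of the 21 members up to 15 passed and their median was 0.04. The 54 other features above 16 had a median of 0.21, and 22 of them were higher.

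**Figure D2:**
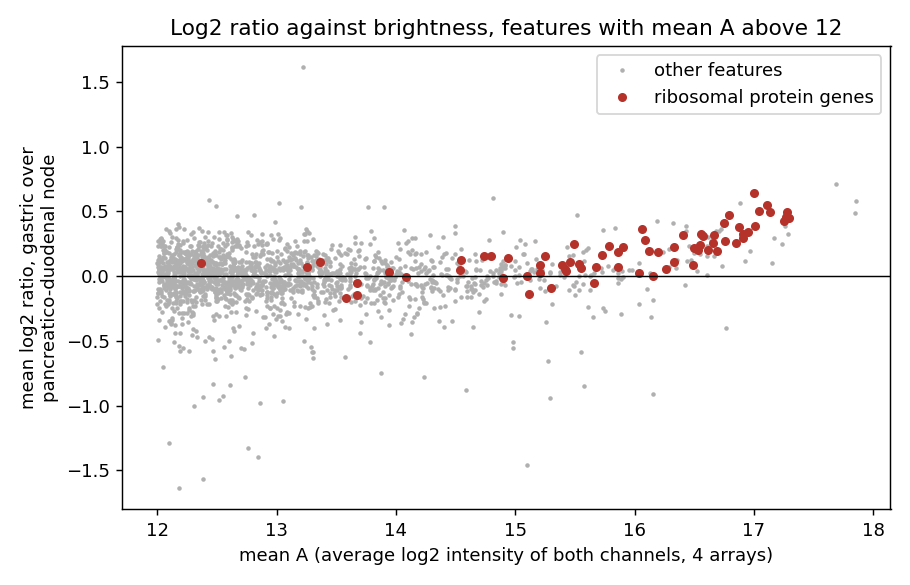
Mean log2 ratio of gastric over pancreatico-duodenal node (vertical axis) against the mean log2 intensity of both channels (horizontal axis) for features with an intensity above 12. Red points are ribosomal protein genes and grey points all other features; above 16 both lie mostly above 0, with medians of 0.31 and 0.21.

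Genes of tissues around the nodes differed from mouse to mouse. None of 29 exocrine pancreas genes passed over the 4 mice, but in mouse 3 all 29 were lower in the gastric node. The list median was -4.72 in mouse 3, against -0.29, 0.21 and 0.45 in mice 1, 2 and 4. The elastase gene Cela3b was at -5.62 in mouse 3 and between -0.77 and 0.69 in the other mice, and the trypsin gene Prss3 was at -5.64 against -0.71 to 0.71. Camera called the list (adjusted p = 0.00144), a call lost with an estimated correlation (adjusted p = 0.773 with an estimated correlation), and without mouse 3 the median was 0.09 with an adjusted p of 0.477. Adipocyte genes also went opposite ways, with list medians of 0.99 in mouse 1, -1.02 in mouse 2, 0.00 in mouse 3 and -0.82 in mouse 4, and none of 20 passed. Fabp4, the fatty acid binding protein gene of adipocytes, was at 1.72 in mouse 1 and at -1.58, -0.73 and -1.70 in mice 2 to 4. None of 10 pancreatic islet genes passed, and Ins2, an insulin gene, was at -0.04 ± 0.44 (SD, n = 4). Ins1 and Il17a were not tested, since their probes were well above background on 1 and 0 arrays in each channel.

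**Figure D3:**
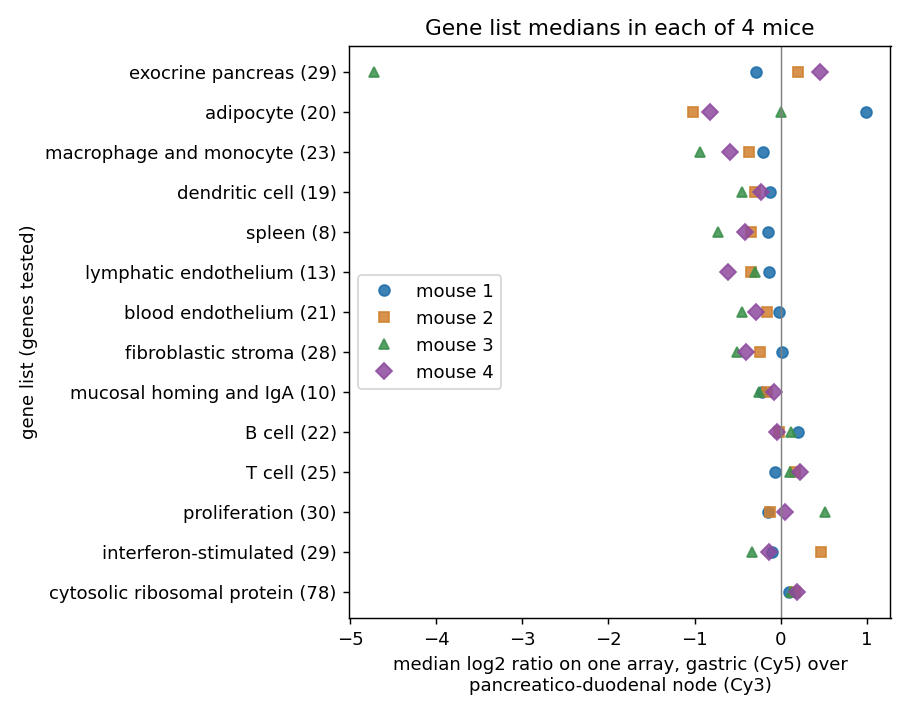
Median log2 ratio of 14 gene lists (vertical axis, with the number of genes tested) in each of the 4 mice, gastric over pancreatico-duodenal node. Each symbol is the median over the list's genes on one array; the exocrine pancreas median of mouse 3 lies at -4.72, the adipocyte medians span -1.02 to 0.99, and the macrophage, dendritic cell, spleen and endothelial medians lie below 0 in 4 of 4 mice after loess.

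Transcriptional regulators of self-antigen genes did not pass. Aire was at -0.12 ± 0.27 (adjusted p = 0.469) and Deaf1 at 0.04 ± 0.10 (SD, n = 4; adjusted p = 0.673), with a further Deaf1 probe at -0.44. Among housekeeping genes, Gusb was lower (-0.36 ± 0.07; adjusted p = 0.0257) and Rplp0, a ribosomal protein gene, was higher (0.29 ± 0.06; adjusted p = 0.0321), with 12 of 14 not passing (3 higher and 4 lower adjusted over the list alone). Rplp0 had a mean log2 intensity of 17.2, in the range where bright features read higher as a group. Actb was at 0.14 ± 0.18 and Gapdh at -0.21 ± 0.14, and neither passed (adjusted p = 0.284 and 0.101). The signs of Gusb and Gapdh turned with median centring. Relative to the median of all features Gusb stayed lower (-0.39 and -0.12), while Gapdh turned from -0.24 to 0.13.

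Stress and cytokine lists held called genes of both signs and were not shifted in the fit to all 4 mice after loess. Among heat shock and unfolded protein response genes, Hspa1b (-0.42 ± 0.19), Atf4 (-0.34 ± 0.03) and Calr (-0.31 ± 0.08) were lower and Hsph1 (0.28 ± 0.09) was higher (SD, n = 4; camera adjusted p = 0.0639; 2 higher and 4 lower adjusted over the list alone). This list was called as lower with scaling between arrays, without mouse 1 and without mouse 2. Among immediate-early genes, Ier3 (-0.45 ± 0.06) and Atf3 (-0.39 ± 0.18) were lower and Dusp2 (0.30 ± 0.07) was higher (camera adjusted p = 0.942; 1 higher and 2 lower adjusted over the list alone). Among inflammatory cytokine and chemokine genes, Ccl11 (-0.72 ± 0.39) and Cxcl5 (-0.58 ± 0.23, well above background on 2 of 4 gastric node arrays) were lower and Il12a (0.30 ± 0.10) was higher (camera adjusted p = 0.846; 2 higher and 2 lower adjusted over the list alone). In the neutrophil list 2 of 11 members were higher, Cxcr2 at 0.54 ± 0.21 (further probe 0.15) and Stfa3 at 0.42 ± 0.17, while the list median was -0.37, or -0.22 without mouse 2 (camera adjusted p = 0.0546; 2 higher and 3 lower adjusted over the list alone). The neutrophil list was called as lower in 9 of 18 alternatives, among them the other offset, no background subtraction and the sets without mouse 1, 2 or 4.

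In the remaining lists few or no genes passed and none of the lists was shifted in the fit to all 4 mice after loess. The mast cell, basophil and eosinophil list had 1 of 11 lower, the protease gene Mcpt1 at -0.59 ± 0.12 (SD, n = 4), well above background on 2 of 4 gastric node arrays. Its size and that of Cxcl5 depended on the processing, with -2.29 and -2.06 in the authors' series table. The mast cell list was called as lower in 5 of 18 alternatives. The thymocyte list had 1 of 6 lower, the antigen-presenting molecule gene Cd1d1 at -0.33 ± 0.15. The oxidative phosphorylation list had 1 of 83 lower, Cox5a at -0.24 ± 0.02, whose direction turned with median centring. No member passed among 29 interferon-stimulated genes, 7 erythroid genes, 8 genes of Th17 and group 3 innate lymphoid cells, 10 gastric mucosa genes, 12 intestinal mucosa genes, 6 hepatocyte genes and 8 skeletal muscle genes. The interferon-stimulated list was called as lower without mouse 2.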

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

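The tests of explanations in this part were all chosen after the values had been seen. Over 149 named genes and list medians, 10 had 1 mouse far from the other mice, where chance alone gives about 1 in 20, and 6.24% of all features met the same criterion. Mouse 1 set apart 713 of these features, and mice 2 to 4 set apart 183, 298 and 136. By correlation mouse 1 did not stand alone. Its ratios correlated with those of mice 2, 3 and 4 at r = 0.41, 0.16 and 0.41. Those of mouse 3 correlated with mice 1, 2 and 4 at 0.16, 0.34 and 0.38, and mice 2 and 4 correlated at 0.64. The cause of these differences between mice was not tested.

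The median of the exocrine pancreas list was -4.72 in mouse 3 and between -0.289 and 0.452 in the other mice. All of its genes brought the difference: 29 of 29 members had their lowest ratio in mouse 3, and 28 of them were below -1 there. Ratios beyond 2-fold were not general on that array, at 0.878% of features outside the list against 96.6% inside it. The list was flagged for its extreme value there, so this contrast does not decide on the quality of the array. The SD of the log2 ratios of all features was 0.34 in mouse 3, against 0.32, 0.23 and 0.21 in mice 1, 2 and 4. Acinar tissue taken along with the pancreatico-duodenal node of mouse 3 may account for the pattern, because acinar cells bring all their abundant transcripts together. The list's 29 genes were well above background in the gastric node channel of every mouse, and no biological explanation was tested. Cela3b and Prss3 were the brightest members, with mean log2 intensities of 12.8 over both channels and 4 arrays.

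The other single-mouse values carry no explanation here. Among increases, Ppp1r14c was at 0.241 in mouse 2 against 1.51 to 1.64 in the other mice, Sh2d1a at 0.273 in mouse 1 against 0.653 to 0.729, and Hsph1 at 0.418 in mouse 1 against 0.23 to 0.245. Among decreases, Dnah2 was at -1.38 in mouse 4 against -2.24 to -2.16, and Cd163 was at -0.821 in mouse 1 against -1.46 to -1.37. In mouse 3, Mcpt1, a mast cell protease gene, was at -0.417 against -0.663 to -0.625, C1qa at -1.26 against -0.861 to -0.78, and Esam at -0.468 against -0.294 to -0.274. The pancreatic islet list median was -0.05 in mouse 1 against 0.0119 to 0.0224.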

How the results depend on the processing

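Leaving out features with a mean intensity above 16 was chosen after seeing the data, and gave 576 higher and 914 lower features and 14 shifted lists, without the ribosomal protein list. All other alternatives were fixed before the data were examined. The counts of 659 higher and 949 lower stayed within 1.5 times under the other offset, no background subtraction, loess on bright probes, both other filters, both other probe rules and the trended robust prior. They fell to 0 and 0 with scaling between arrays. Leaving out 1 mouse gave 0 to 844 higher, 0 to 1323 lower and 12 to 21 shifted lists. With fewer mice the test has fewer degrees of freedom, but the cause of the rise without mouse 1 was not tested. Array weights gave 2120 and 2211, an adjusted p under 0.10 gave 2151 and 2055, and a test against a fold of 1.2 gave 0 and 12 (664 at an unadjusted p under 0.05). Without the replicate block, with both channels as unpaired samples, the counts were 335 and 568. The scanner software's ratio gave 477 higher and 572 lower, and with the authors' series table the counts were 489 and 584. Of the 1608 features called here, only 710 and 722 were called with the same sign under these 2 settings. Sizes of some dim genes grew with that table, from -0.59 to -2.29 for Mcpt1, -0.58 to -2.06 for Cxcl5, -0.34 to -0.89 for Krt7 and -1.26 to -2.19 for Cd163. The list count went from 15 to 0 with an estimated correlation, where the smallest unadjusted p was 0.0520, and to 2 with fry, circadian clock and ribosomal protein. Elsewhere calls were gained by the lists for neutrophil (9 of 18 alternatives, median centring included), mast cell (5, median centring included), heat shock (scaling, without mouse 1 or 2), proliferation (without mouse 1 or 2), adipocyte and cytotoxic cell (without mouse 1), interferon (without mouse 2) and skeletal muscle (no filter on dim probes). The cause of these changes was not tested.

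Median centring in place of loess moved the median of all features from 0.03 to 0.32 and gave 12821 higher and 2066 lower, so that 86.1% of calls were higher against 41.0% before. The unremoved trend with intensity is the construction of that setting. Among values called in either setting, signs turned for Aire (0.38), Atf4 (0.15), Calr (0.30), Ccr9 (0.35), Cd1d1 (0.27), Cox5a (0.47), Eng (0.0224), Esam (0.0891), Gapdh (0.46), Gusb (0.20), Lgals4 (0.43), Madcam1 (0.28), Mylpf (0.29), Per1 (0.10), Plvap (0.0539), Tap2 (0.0881), Tnni2 (0.25) and Xbp1 (0.26). Among lists called in either setting, medians turned for islet (-0.0547), gastric mucosa (-0.0469), adipocyte (0.17), plasma cell (0.48), macrophage (0.15), spleen (0.0358), blood endothelium (0.23), fibroblastic stroma (0.0691), smooth muscle (0.18), mucosal homing (0.38), circadian clock (0.27) and MHC (0.63). The calls of plasma cell, blood endothelium, smooth muscle, mucosal homing and circadian clock were lost, and MHC was called in the other direction. Newly called there were islet, gastric and intestinal mucosa, adipocyte, B cell, mast cell, neutrophil, oxidative phosphorylation and housekeeping lists. Relative to the median of all features, 80 of 81 called named genes (not Cox5a) and 12 of 15 called lists (not plasma cell, mucosal homing and MHC) kept their direction. Leaving out 1 mouse put the exocrine pancreas median between -1.54 and 0.0909, the latter without mouse 3. Of 2098 values of named genes under alternatives, 1611 stayed on their side of the threshold (28 of them uncalled values whose sign turned), 444 lost the call, 25 gained it and 18 turned; none of the 81 called genes kept its call under every alternative.

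The 8 distinct sign patterns of the 4 arrays are too few for a share under 0.05. The real pattern gave 1608 called features, as the only 1 with as many, against 0 in the highest other. It gave 15 called lists, and 4 patterns, the real one included, gave as many or more, with 18 in the highest other. Slide and scan as batches were not run, since all arrays share 1 of each, nor was a base content correction. Signal over background limited the pancreatico-duodenal channel more, with at most 62.6% of probes well above background.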

Other observations

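The tests of explanations in this part were all chosen after the values had been seen. Several gene lists, or some of their members, differed between mice. The interferon-stimulated list had a median of 0.47 in mouse 2 and of -0.10, -0.33 and -0.14 in mice 1, 3 and 4, and none of its 29 genes passed over the 4 mice. The proliferation list had a median of 0.51 in mouse 3 and of -0.15, -0.13 and 0.05 in mice 1, 2 and 4. Of 7 erythroid genes, 2 lay above 1 in mice 1 and 4, the haemoglobin gene Hba-a1 at 2.20 and 2.98 against 0.15 and 0.52 in mice 2 and 3, and the haem synthesis gene Alas2 at 1.60 and 1.61 against 0.02 and 0.13. The erythroid list medians were only 0.23, 0.10, 0.13 and 0.25 in mice 1 to 4. In the neutrophil list 4 of 11 members lay below -1 in mouse 2, the lowest at -4.03, and none in mice 1 and 4.

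The ribosomal protein genes were higher in the gastric node where their probes were bright. The 21 members with a mean intensity up to 15 had a median of 0.0425 (95% bootstrap interval -0.0227 to 0.0988), below 0.156, which is the bright members' median divided by 2. The rise was thus not seen in the dim members. This does not decide on a rise of the whole class. Dim probes may read these transcripts poorly, and the list, set by a pattern of gene names, can hold paralogs. A dye effect at the bright end that loess left in place stays open. Against the 3 other features nearest in intensity, the members were higher by a median of 0.0697 (0.0389 to 0.0997), an interval that holds 0.0782, the list median divided by 2. The node as a biological cause stays untested, since node and dye go together on every array.

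The lower macrophage, dendritic cell, endothelial and stromal genes are the pattern most open to follow-up. A dye effect of the single probe is argued against for the sign only, because 13 of 14 further probes of 11 called genes of these lists were also below 0. The exact 95% interval of 66.1% to 99.8% treats these probes as independent. Over all called genes, 383 of 462 further probes had the sign of the brightest. Some sizes depended on the probe, with Col3a1 at -0.84 and -0.12 and Adgre1 at -1.36 and -0.54. Serpinf1 was closer, at -0.81 and -0.66. A lower share of lymphocytes in the pancreatico-duodenal node stays open too. Had it alone lowered the medians of all lists of other cell types alike, those of macrophages and blood endothelium would have been equal. The macrophage median lay below that of blood endothelium in 4 of 4 mice, by -0.295 ± 0.134 (SD, n = 4). Unequal medians do not decide this, since the genes of these lists may differ in how far lymphocytes express them. The lymphatic endothelium medians were -0.14, -0.34, -0.30 and -0.61 in mice 1 to 4. Those of macrophages were -0.21, -0.37, -0.94 and -0.59. A dye effect of the whole transcript cannot be told apart from the node, as the arrays have 1 dye orientation. Surrounding tissue taken along with a node also stays open. The adipocyte medians were 0.99, -1.02, 0.00 and -0.82 in mice 1 to 4 and the stromal ones 0.02, -0.25, -0.51 and -0.40, and mouse 3 had the low exocrine pancreas median of -4.72. A hypothesis left open is that the right node may hold more macrophages and Aldh1a2-expressing dendritic cells, or that these express more of the genes. Macrophage genes did not all go that way. Of 23 members 10 were lower in the gastric node, 1 was higher and 12 did not pass. Lyz2 lay between -0.29 and 0.07, and Folr2 (0.74) and the myeloid receptor gene Trem2 (0.62) were higher. Arrays with exchanged dyes would separate the dye from the node, but not cell number from expression per cell, which these data do not test.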
